A study of Mus musculus with 24 samples.

How the data were processed

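The data are RNA sequencing counts of 24 libraries of mouse heart fibroblasts, 3 for each of 4 conditions (control, Erg, Sox17 and SEG) at day 3 and day 7, grown in EGM2. Per the labels' protocols, RNA was taken with an RNeasy kit and messenger RNA libraries were made by Novogene. The deposited table holds whole-number counts per gene, not normalized, for 35727 Ensembl gene identifiers. Of these, 35422 carried a gene name and 305 did not. Per the submitters' processing notes, Salmon and DESeq2 were used and the build was mm10; their versions, their order, the annotation release, the strand setting and any rounding of estimated counts are not given in the sources used here. Salmon estimates counts from transcripts, so genes that share sequence with close relatives, such as histocompatibility genes, are uncertain. Each column was matched to its library by the name in the library's label.

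Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes passed filterByExpr at its minimum count of 10, which left 14804, and libraries were scaled by TMM. Total counts per library ran from 18794422 to 44586227. The floor of a group at 0 counts was 3 counts over its 3 libraries, and intervals of ratios against 1 to 3 counts were 95% counting intervals. CPM in the text is relative to the TMM-scaled library size, as mean ± SD over 3 libraries, and log2 changes are those of edgeR's fit at its preset prior count of 0.125, while log2 CPM, for principal components and list tests, had a prior count of 2. Coordinates and gene types are from GENCODE's mouse annotation of mm10.

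A quasi-likelihood model with 8 group means was fitted to all 24 libraries, which share an estimate of the spread. In all, 19 comparisons were tested 2-sided, with Benjamini-Hochberg adjusted p under 0.05 as a call: each factor against control at each day, SEG against each factor at each day, day 7 against day 3 in each condition, the change of each effect between the days, and SEG against the sum of both log2 effects at each day. For 22 lists of endothelial, fibroblast, contractile, immune, other cell type and pathway genes, members called up and down were counted over all genes tested and adjusted over the list alone. Camera was run on log2 CPM with its preset correlation of 0.01 and with an estimated correlation, beside fry, and adjusted over the lists within a comparison. Of 308 list tests, 124 were called with the preset correlation and 50 with the estimated one. A call given without the second p holds with it.

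Conditions, lists and settings were chosen before the data were examined, and so was the rule for the genes named. It takes Sox17 and Erg, the 10 largest rises and 10 largest falls among called genes with at least 10 CPM in the higher group and no overlap of libraries (5 and 5 for the last 2 kinds of comparison), up to 4 called members of each list with the largest change, and a fixed set of endothelial, fibroblast, contractile and other marker genes. Genes without a name or with a predicted name were skipped. As alternatives, RLE size factors, no filter on low counts, a replicate block, a test of changes beyond 1.5-fold, fits of only the groups compared, DESeq2 1.42.0 and leaving out each library were run. Leaving out both outlying day 7 libraries (replicate 1 of Sox17 and of SEG), and a replicate block within Sox17 and SEG at day 7 alone, were added after the data were seen.

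The tests were checked on counts simulated from each gene's mean over all 24 libraries, the real library sizes and the trend of the spread. Genes were drawn independently, few of them changed, and no library was made to deviate. The false calls below hold for that setting and do not carry over to data with wide changes and outlying libraries. For SEG against control at day 7, 73 of 100 genes changed 2-fold and 94 of 100 changed 4-fold were called, with 7 false calls among 14804 genes. For the change of the SEG effect between the days, 31 of 100 and 83 of 100 were called, with 8 false calls. No pair of libraries was alike within sampling noise, so each library counts once. Tables were made with pandas 2.3.3 and figures with matplotlib 3.10.9 in Python 3.11.15.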

Results

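Messenger RNA was sequenced from mouse heart fibroblasts kept in EGM2, a growth medium made for endothelial cells. The labels name 4 conditions, control, Erg, Sox17 and SEG, each harvested at day 3 and at day 7, and leave SEG without a fuller name, so whether it holds a factor besides Erg and Sox17 is not known. Each of the 8 groups held 3 libraries, which makes 24 in all. The study compared the conditions to see how far the cells took on endothelial gene expression. Nothing in the labels says that the libraries of a group came from separate cultures or animals, so p-values measure the spread between these libraries, which may be technical.

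Total counts per library ran from 18794422 to 21332347 in control at day 3 and from 19183807 to 24782231 at day 7. With Erg they ran from 19152711 to 37355910 at day 3 and from 18830407 to 30918243 at day 7, and with Sox17 from 22496193 to 35229998 and from 24090381 to 44586227. SEG libraries held 19467852 to 26827713 counts at day 3 and 20438305 to 24369257 at day 7. The first principal component of the tested genes carried 38.1% of the variance and the next 19.9%. Replicate 1 of Sox17 at day 7 stood apart from the rest of its group. Genes of ribosomal proteins took 7.23% of its counts and mitochondrial genes 0.880%, against 2.90% to 4.57% and 1.39% to 2.01% in the libraries other than it and replicate 1 of SEG at day 7, where ribosomal protein genes took 4.99%. Both are called the outlying day 7 libraries here.

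**Figure D1:**
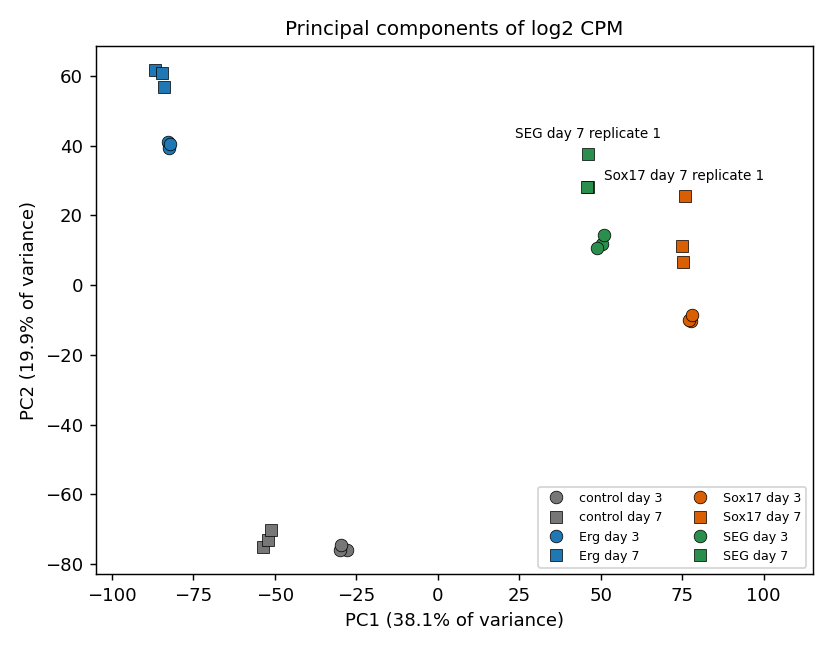
Principal components 1 (38.1% of the variance) and 2 (19.9%) of log2 CPM of the tested genes, 1 point per library, with colours for the 4 conditions, circles for day 3 and squares for day 7. Libraries of a group lie together, and replicate 1 of Sox17 at day 7 lies away from the other libraries of its group.

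Sox17 and Erg were looked at first, because the conditions carry their names. Sox17 (ENSMUSG00000025902, chromosome 1, 4490931 to 4497354, minus strand of mm10, protein coding) encodes a transcription factor of endoderm and arterial endothelium. It had 0 counts in all 6 control libraries, which allows up to 0.0520 CPM over the 3 libraries of day 3 and 0.0474 CPM over those of day 7. With Sox17 it reached 1606 ± 53 CPM at day 3 and 1080 ± 402 CPM at day 7 (SD, n = 3), and in SEG 1008 ± 49.9 and 699 ± 206 CPM. Erg libraries held between 2 and 9 counts of it. Erg (ENSMUSG00000040732, chromosome 16, 95359169 to 95586593, minus strand, protein coding), an ETS family transcription factor of endothelium, reached 7087 ± 46.9 CPM at day 3 and 5138 ± 751 CPM at day 7 with Erg. In SEG it reached 1268 ± 13.7 and 961 ± 109 CPM, and elsewhere it had 0 to 3 counts per library.

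Both genes lay on the side that the label names in 24 of 24 libraries, with SEG taken to name both, which its label does not spell out. SEG exceeded control at least 19400-fold for Sox17 at day 3 and at least 15000-fold at day 7. The ratio for Erg was 36500 at day 3 (95% counting interval 10100 to 301000) and 30600 at day 7 (8470 to 253000). Erg was lower in SEG than with Erg alone, with a ratio of means of 0.179 at day 3 and 0.187 at day 7 (log2 change −2.48, adjusted p = 2.18e-09, and −2.42, adjusted p = 3.29e-09). Sox17 in SEG stood at 0.628 and 0.647 times its level with Sox17 alone, and neither difference passed (adjusted p = 0.0948 and 0.0909). Without both outlying day 7 libraries, a choice made after the data were seen, both did (log2 change −0.68 at either day), as did the day 7 difference without replicate 1 of Sox17 (−0.91) and with a replicate block within Sox17 and SEG at day 7 (−0.59, also chosen after the data were seen), and the day 3 difference in a fit of only the groups compared (−0.68). Counts per gene do not tell an introduced copy from the cells' own, and intervals and floors cover counting error only.

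**Figure D2:**
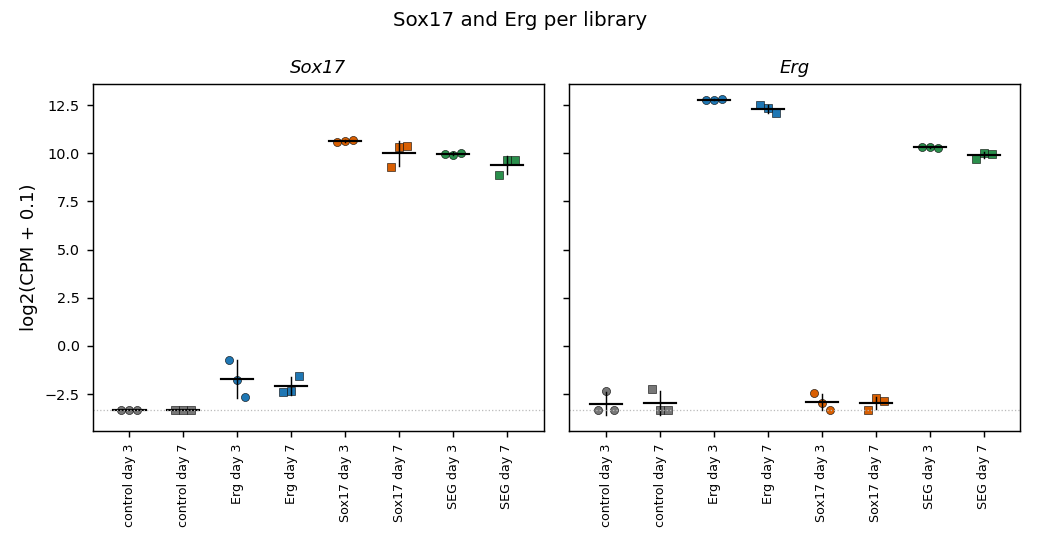
CPM of Sox17 and Erg on a log2 scale after adding 0.1 CPM, 1 point per library, for control, Erg, Sox17 and SEG at day 3 (circles) and day 7 (squares), with bars for mean ± SD and a dotted line for 0 counts. Sox17 is high in the Sox17 and SEG libraries and Erg in the Erg and SEG libraries, and Erg is lower in SEG (1268 CPM at day 3) than with Erg alone (7087 CPM).

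SEG against control asked how many endothelial genes the cells of that condition expressed. At day 3, Cdh5, the adherens junction cadherin of endothelium, stood at 645 ± 29.8 CPM in SEG against 0.519 ± 0.261 in control (SD, n = 3; log2 change 10.26). Kdr, the main receptor of vascular endothelial growth factor, stood at 288 ± 26.1 against 0.878 ± 0.334 CPM, Tie1, a receptor tyrosine kinase of endothelium, at 221 ± 13.8 against 0.0729 ± 0.0858, and Pecam1, a junctional adhesion molecule, at 69.7 ± 5.89 against 0.262 ± 0.156. Emcn, an endothelial sialomucin, reached 225 ± 2.18 CPM (log2 change 9.83). Robo4, a guidance receptor of endothelium, reached 20.8 ± 0.404 CPM from 0 counts, at least 400-fold higher. Of 31 tested genes of the endothelial core list, 27 rose, 3 fell and 1 did not pass, with the same 27 and 3 adjusted over the list alone. Their median log2 change was 5.94, or 4.37 with genes at 0 counts set to their bound (camera adjusted p = 2.77e-15). Cd34, a sialomucin of endothelial and stromal progenitors, fell by 1.55 on the log2 scale, and Vwf, von Willebrand factor, had a log2 change of 0.21 (adjusted p = 0.687). Nos3, the endothelial nitric oxide synthase, rose by 2.49 and Tek, the angiopoietin receptor, by 1.08.

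Arterial and Notch pathway genes rose in the same comparison. Gja5, a connexin of arterial endothelium (chromosome 3, 96904693 to 97077416, plus strand), reached 597 ± 4.77 CPM, a ratio of 17200 to control (95% counting interval 4760 to 142000). Dll4, a Notch ligand of arterial and tip cells, reached 102 ± 2.85 CPM (log2 change 10.42), Hey1, a Notch target repressor, 40.7 ± 3.09 against 0.633 ± 0.273 CPM, and Efnb2, the arterial ephrin, 283 ± 22.1 against 18.1 ± 3.13 CPM. Of 25 tested members, 20 rose, 3 fell and 2 did not pass, with 20 and 3 adjusted over the list alone (median 2.72, camera adjusted p = 3.18e-12). Of 21 endothelial transcription factors, 11 rose, 4 fell and 6 did not pass, with 13 and 4 adjusted over the list alone. Sox7, an F group SOX factor, rose by 2.14 and Bcl6b by 6.32, whereas Fli1, an ETS factor, fell by 0.54 and Gata2 by 0.71, falls that a test beyond 1.5-fold did not pass. Camera called that list with adjusted p = 0.00499, and adjusted p = 0.412 with an estimated correlation.

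Fibroblast genes moved the other way at day 3. Pdgfra, the platelet-derived growth factor receptor of fibroblasts, stood at 113 ± 8.72 CPM in SEG against 638 ± 11.1 in control, Col3a1, a fibrillar collagen, at 1175 ± 97.0 against 4522 ± 348, and Dcn, the proteoglycan decorin, at 162 ± 10.4 against 684 ± 52.9. Of 32 members, 23 fell, 4 rose and 5 did not pass, with 24 and 4 adjusted over the list alone (median −1.13, camera adjusted p = 1.6e-10). All 17 called members of the interferon response list fell, of 20 tested, with 19 adjusted over the list alone. Ifit3, an antiviral effector, stood at 30.8 ± 12 against 289 ± 43.4 CPM. The interferon call (adjusted p = 5.02e-07) had adjusted p = 0.263 with an estimated correlation. Of 26 cell cycle genes, 13 fell, 1 rose and 12 did not pass, with 15 and 1 adjusted over the list alone (camera adjusted p = 0.00105, and adjusted p = 0.201 with an estimated correlation). The largest falls included Plin4, a lipid droplet protein (log2 change −5.33), Cemip, a hyaluronan-binding protein (−4.95), and Tgfbi, a matrix protein (−4.85). In all, 2958 genes were higher and 2988 lower in SEG at day 3, of 14804 tested by edgeR's quasi-likelihood test.

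At day 7, Cdh5 stood at 901 ± 152 CPM in SEG against 0.152 ± 0.110 in control (log2 change 12.44), and Pecam1 at 200 ± 14.9 CPM (7.74). Tie1 reached 533 ± 7.83 CPM, a ratio of 11200 (95% counting interval 3840 to 54500), and Kdr 235 ± 45.2 against 1.26 ± 0.398 CPM. Robo4 reached 91.6 ± 5.90 CPM, a ratio of 1930 (658 to 9340). Cldn5, an endothelial tight junction claudin, reached 6.36 ± 1.30 CPM, at least 133-fold over control. Vwf rose by 3.91, to 24.6 ± 11 CPM, Cd34 fell by 3.10, and Nos3 was at or under the floor in both groups. Among the 31 endothelial core genes, 25 rose, 3 fell and 3 did not pass, with 25 and 3 adjusted over the list alone (median 4.24, or 4.53 with genes at 0 counts at their bound and Nos3 left out, camera adjusted p = 1.25e-13).

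Among arterial genes at day 7, Gja5 stood at 875 ± 26.4 CPM in SEG (log2 change 13.64), Sema3g, a secreted semaphorin of arteries, at 468 ± 54.5 (11.99), Dll4 at 265 ± 3.38 (11.63) and Hey1 at 173 ± 4.19 CPM (8.40). Of 25 members, 21 rose, 3 fell and 1 did not pass, with 21 and 3 adjusted over the list alone (median 3.13, camera adjusted p = 2.41e-12). Pdgfb, a growth factor that recruits mural cells, reached 170 ± 1.12 CPM (11.29), and Mcam, an adhesion molecule of vessels, 351 ± 9.90 against 2.17 ± 0.384 CPM. Of 21 endothelial transcription factors, 10 rose, 5 fell and 6 did not pass, with 11 and 5 adjusted over the list alone (camera adjusted p = 0.0185, and adjusted p = 0.435 with an estimated correlation). Fli1 fell by 0.93 and Gata2 by 1.03.

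Fibroblast genes at day 7 in SEG included Dcn at 69.0 ± 7.77 CPM against 1266 ± 105 in control, Pdgfra at 34.9 ± 9.45 against 801 ± 56.5, Dpt, a dermatopontin of the matrix, at 6.89 ± 0.783 against 426 ± 25, and Gsn, the actin-severing gelsolin, at 333 ± 51.8 against 11600 ± 727. Of 32 members, 19 fell, 6 rose and 7 did not pass, with 21 and 7 adjusted over the list alone (median −0.92, camera adjusted p = 5.12e-07). Col1a1, the main fibrillar collagen chain, rose by 0.46 (adjusted p = 0.00201), which did not pass a test beyond 1.5-fold. Contractile genes rose, 15 of 18 with none falling and 3 not passing, and 15 adjusted over the list alone (median 2.10, camera adjusted p = 9.24e-09). Acta2, smooth muscle actin, stood at 1116 ± 138 against 64.8 ± 6.14 CPM, Tagln, an actin-binding protein of smooth muscle, at 472 ± 78.4 against 26.2 ± 3.44, and Myh11, smooth muscle myosin, rose by 5.41.

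Cell cycle genes rose against control at day 7, 15 of 26 with 1 falling, and 18 and 1 adjusted over the list alone, with Ccna2, a mitotic cyclin, up by 0.82 and Cdc20, an activator of the anaphase complex, by 1.75 (camera adjusted p = 0.000579, and adjusted p = 0.135 with an estimated correlation). Sterol and fatty acid synthesis genes fell, 14 of 16 with none rising, and 14 adjusted over the list alone. Hmgcs1, an enzyme of cholesterol synthesis, fell by 1.41 and Scd1, a fatty acid desaturase, by 1.43 (camera adjusted p = 5.12e-07, and adjusted p = 0.103 with an estimated correlation). Of 16 inflammatory genes, 10 fell, 3 rose and 3 did not pass, alike adjusted over the list alone (camera adjusted p = 0.00265). C3, a complement component, stood at 26.6 ± 4.60 against 2438 ± 299 CPM, and Lcn2, an acute phase lipocalin, fell by 5.67. C7, a late complement component of fibroblasts, had 0 counts in SEG and 25.8 ± 5.26 CPM in control, at least 588-fold lower. In all, 3336 genes were higher and 3221 lower.

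**Figure D3:**
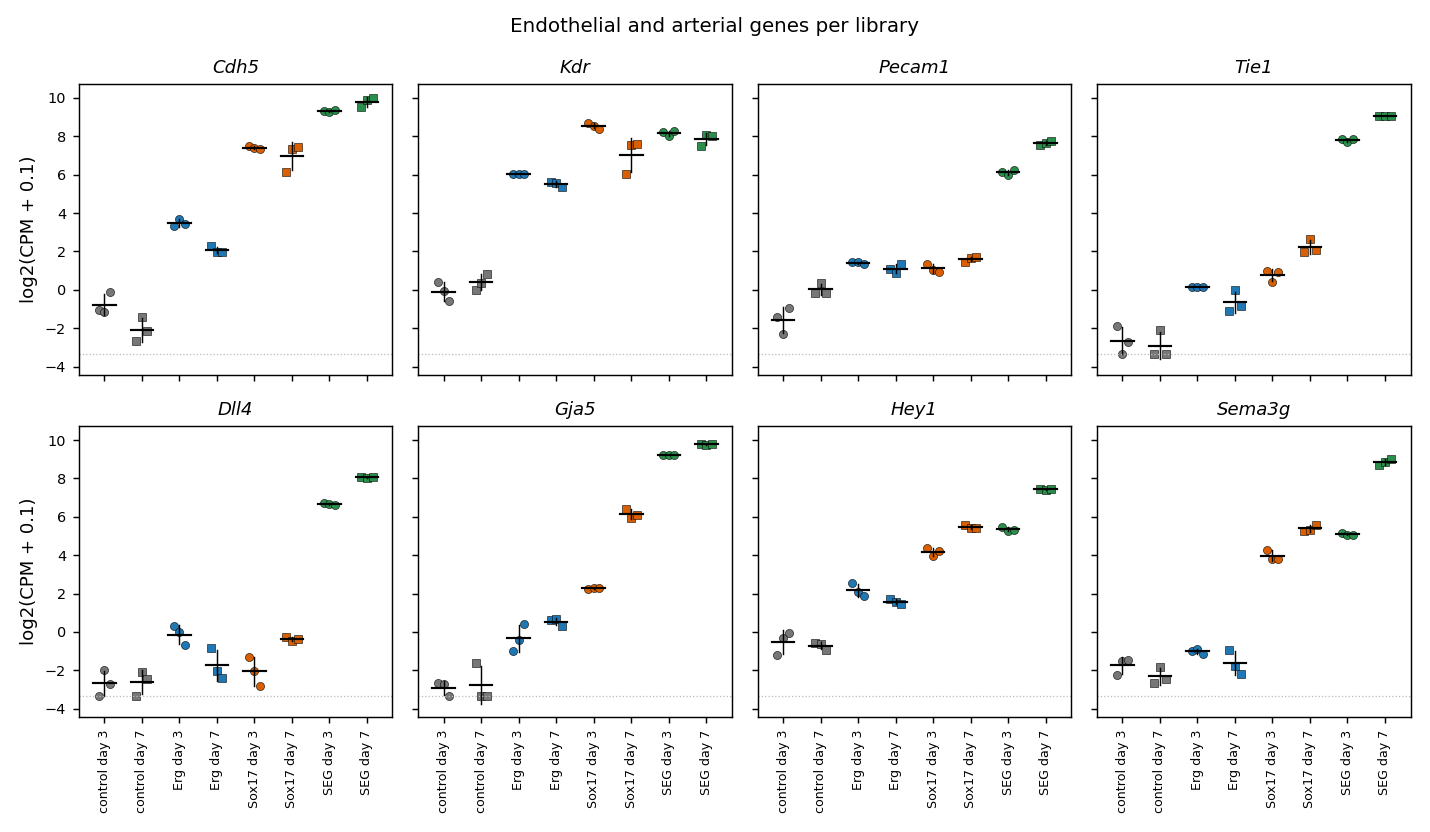
CPM of endothelial and arterial genes on a log2 scale after adding 0.1 CPM, 1 point per library, for each condition at day 3 (circles) and day 7 (squares), with bars for mean ± SD and a dotted line for 0 counts. SEG libraries reach 645 CPM of Cdh5 at day 3 and 901 CPM at day 7, against 0.519 and 0.152 CPM in control.

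Erg against control asked what that factor did alone. At day 3, Apln, the peptide apelin of tip cells, stood at 722 ± 27.6 CPM against 7.04 ± 1.05 (SD, n = 3; log2 change 6.68), Lyve1, a hyaluronan receptor of lymphatic endothelium, at 142 ± 6.95 (6.23), Jag2, a Notch ligand, at 126 ± 1.59 (9.47) and Esam, an endothelial adhesion molecule, at 84.7 ± 3.08 CPM (9.04). Flt1, a receptor of vascular endothelial growth factor, stood at 204 ± 3.84 against 11.5 ± 1.55 CPM. Sox18, an F group SOX factor, reached 28.2 ± 1.79 CPM, a ratio of 1600 (95% counting interval 286 to 63100). Cdh5 and Pecam1 rose by 4.40 and 3.28, to 11.1 ± 1.57 and 2.57 ± 0.0876 CPM. In the endothelial core list of 31, 20 rose, 1 fell and 10 did not pass, with 21 and 1 adjusted over the list alone (median 3.11, or 2.75 with genes at 0 counts at their bound, camera adjusted p = 1.75e-08). Of 25 arterial genes, 11 rose, 7 fell and 7 did not pass, and camera made no call (adjusted p = 0.168). Of 21 endothelial transcription factors, 12 rose and 4 fell, with 13 and 4 adjusted over the list alone (camera adjusted p = 0.0138, and adjusted p = 0.34 with an estimated correlation). Of 18 macrophage genes, 8 rose and 1 fell, alike adjusted over the list alone (median 0.58, camera adjusted p = 0.0434, and adjusted p = 0.34 with an estimated correlation), a call that did not pass without replicate 3 of control, 1 of Erg or 2 of Erg at day 3 (range over the alternatives 0.0164 to 0.0848).

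Cell cycle genes fell with Erg at day 3, 24 of 26 with 2 rising, and alike adjusted over the list alone (median −1.43, camera adjusted p = 2.11e-11). Mki67, a proliferation marker, stood at 24 ± 4.63 CPM in these cells, a log2 change of −1.71, and Ccna2 fell by 1.82. Of 20 interferon genes, 17 fell and none rose, with 17 adjusted over the list alone (camera adjusted p = 6.28e-06, and adjusted p = 0.291 with an estimated correlation). Of 16 sterol and fatty acid genes, 13 fell and none rose, with 13 adjusted over the list alone (camera adjusted p = 0.000141, and adjusted p = 0.233 with an estimated correlation). Of 32 fibroblast genes, 16 fell, 5 rose and 11 did not pass, without a camera call (adjusted p = 0.0784). Col3a1 fell by 1.05 and Pdgfra by 1.71, whereas Dcn rose by 0.66, which did not pass a test beyond 1.5-fold. Among the largest rises were Wnt9b, a Wnt ligand, at 30.7 ± 3.11 CPM from 0 counts, at least 575-fold higher, and Vipr1, a receptor of vasoactive intestinal peptide (log2 change of 10). Ephb2, an ephrin receptor, fell by 2.99 and F3, tissue factor, by 2.96. In all, 3344 genes were higher and 3483 lower.

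At day 7 with Erg, Kdr stood at 45.9 ± 4.72 CPM (log2 change 5.16), Esam at 67.0 ± 2.83 (8.54), Sox18 at 25.1 ± 1.05 (7.76), Flt1 at 84.5 ± 11.1 against 25.6 ± 2.06 (1.72) and Cdh5 at 4.16 ± 0.515 CPM (4.68). Of the 31 endothelial core genes, 20 rose, 2 fell and 9 did not pass, alike adjusted over the list alone (median 1.72, or 1.63 with genes at 0 counts at their bound, camera adjusted p = 1.6e-06). Macrophage genes rose, 17 of 18 with 1 falling, and alike adjusted over the list alone (median 2.34, camera adjusted p = 4.9e-09). Fcgr1, an Fc receptor of macrophages, stood at 8.10 ± 0.837 CPM, Ptprc, the leukocyte antigen CD45, at 5.93 ± 1.61 against 1.10 ± 0.126, and Spi1, a myeloid transcription factor of the blood list, rose by 2.57. These markers of another cell type moved with the endothelial core genes of this comparison. Sterol and fatty acid genes fell, 16 of 16, also adjusted over the list alone (median −1.67, camera adjusted p = 2.72e-12), with Scd1 at 77.9 ± 3.33 against 443 ± 50 CPM. Of 32 fibroblast genes, 23 fell, 3 rose and 6 did not pass, alike adjusted over the list alone (median −1.23, camera adjusted p = 8.48e-08). Col1a1 stood at 3314 ± 210 against 7776 ± 248 CPM, and Mfap4, a microfibril protein, fell by 4.43.

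Cell cycle genes rose with Erg at day 7, 17 of 26 with none falling, and 17 adjusted over the list alone (median 0.46, camera adjusted p = 0.000112, and adjusted p = 0.134 with an estimated correlation). Contractile genes rose, 10 of 18 with 4 falling, and 11 and 4 adjusted over the list alone, with Tagln at 267 ± 3.18 CPM (log2 change 3.35) and Acta2 up by 1.85. That contractile call (camera adjusted p = 0.0111) had adjusted p = 0.224 with an estimated correlation. Without both outlying day 7 libraries, a choice made after the data were seen, it did not pass (adjusted p = 0.0534, range over the alternatives 0.00252 to 0.0534). In all, 3512 genes were higher and 3670 lower.

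Sox17 against control asked the same of that factor. At day 3, Kdr stood at 377 ± 37.0 CPM (SD, n = 3; log2 change 8.75), Cdh5 at 171 ± 11.2 (8.35), Igfbp3, an insulin-like growth factor binding protein of the arterial list, at 1855 ± 42.6 against 54.0 ± 1.73 (5.10), and Bmx, a cytoplasmic tyrosine kinase of arteries, at 147 ± 18.1 CPM (4.82). Hey1 stood at 18.1 ± 2.69 CPM, Efnb2 at 226 ± 7.16, and Gja5 at 4.74 ± 0.131, a ratio of 136 (95% counting interval 37.5 to 1130). Of 25 arterial genes, 18 rose, 5 fell and 2 did not pass, alike adjusted over the list alone (median 1.99, camera adjusted p = 1.48e-05, and adjusted p = 0.0742 with an estimated correlation). Among the 31 endothelial core genes, 16 rose, 5 fell and 10 did not pass, with 18 and 6 adjusted over the list alone (median 1.17, or 1.27 with genes at 0 counts at their bound and 3 genes at or under the floor in both groups left out, camera adjusted p = 0.00242). Pecam1 reached 2.08 ± 0.338 CPM (2.99), Flt1 fell by 1.28 and Cd34 by 3.69. Of 21 endothelial transcription factors, 4 rose and 7 fell, without a camera call (adjusted p = 0.241).

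Fibroblast genes fell with Sox17 at day 3, 25 of 32 with 2 rising, and alike adjusted over the list alone (median −1.54, camera adjusted p = 7.56e-12). Col3a1 stood at 574 ± 27.8 CPM (log2 change −2.98) and Dcn at 108 ± 6.45 (−2.66). Contractile genes rose, 11 of 18 with 2 falling, and 12 and 2 adjusted over the list alone, with Acta2 at 1420 ± 278 CPM and Cnn1, a calponin of smooth muscle, at 28.7 ± 7.02 against 1.14 ± 0.208. That contractile call (camera adjusted p = 0.00242) had adjusted p = 0.125 with an estimated correlation. Of 20 interferon genes, 17 fell and none rose, with 18 adjusted over the list alone (camera adjusted p = 4.1e-06, and adjusted p = 0.238 with an estimated correlation). Pmch, a hypothalamic neuropeptide precursor, reached 106 ± 5.64 CPM, a ratio of 3050 (845 to 25200), and Magix, a PDZ domain protein, at least 1140-fold the control level. Hp, the acute phase haptoglobin, fell by 5.82, Tgfbi by 5.12 and Sox9, a transcription factor of cartilage, by 3.82. In all, 3082 genes were higher and 2905 lower.

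At day 7 with Sox17, Gja5 stood at 71.3 ± 12.2 CPM (log2 change 10.03), Pdgfb at 60.2 ± 9.13 (9.79), Sema3g at 42.2 ± 4.96 (8.51), Hey1 at 44.3 ± 2.86 (6.44), Cdh5 at 135 ± 55.4 (9.70) and Kdr at 148 ± 71.5 CPM (6.84). Of 25 arterial genes, 19 rose, 3 fell and 3 did not pass, alike adjusted over the list alone (median 1.91, camera adjusted p = 3.36e-05, and adjusted p = 0.0527 with an estimated correlation). In the endothelial core list of 31, 17 rose, 8 fell and 6 did not pass, with 18 and 8 adjusted over the list alone (median 1.08, or 1.18 with 1 gene at or under the floor in both groups left out, camera adjusted p = 0.0197). Pecam1 rose by 1.64, Flt1 fell by 1.89 and Cd34 by 4.70. Without both outlying day 7 libraries, a choice made after the data were seen, the core call did not pass (adjusted p = 0.0560, range over the alternatives 0.0108 to 0.0560).

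Contractile genes rose with Sox17 at day 7, 14 of 18 with 1 falling, and alike adjusted over the list alone (median 1.65, camera adjusted p = 2.31e-06), with Acta2 at 2199 ± 683 CPM (log2 change 5.09), Tagln at 899 ± 390 (5.10) and Cnn1 at 62.1 ± 27.1 against 0.127 ± 0.0499. Cell cycle genes rose, 26 of 26, also adjusted over the list alone (median 1.34, camera adjusted p = 1.82e-11), with Mki67 at 46.9 ± 7.24 against 15 ± 3.43 CPM. Interferon genes fell, 20 of 20, also adjusted over the list alone, with Ifi44, an interferon-induced protein, at 10.6 ± 3.58 against 200 ± 14.2 CPM (camera adjusted p = 2.31e-06, and adjusted p = 0.2 with an estimated correlation). Of 32 fibroblast genes, 23 fell, 4 rose and 5 did not pass, with 24 and 4 adjusted over the list alone (median −1.73, camera adjusted p = 4e-10). Lum, the proteoglycan lumican, fell by 6.61, Dcn by 4.47 and Dpt by 5.89. Of 16 inflammatory genes, 10 fell and 2 rose, alike adjusted over the list alone (camera adjusted p = 0.00324). C7 had 0 counts with Sox17, at least 903-fold lower, and Hp fell by 9.15. The ribosomal protein share of 7.23% in replicate 1 stands within this group. In all, 4366 genes were higher and 3696 lower, 8062 together. A fit of only the groups compared called 4314.

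**Figure D4:**
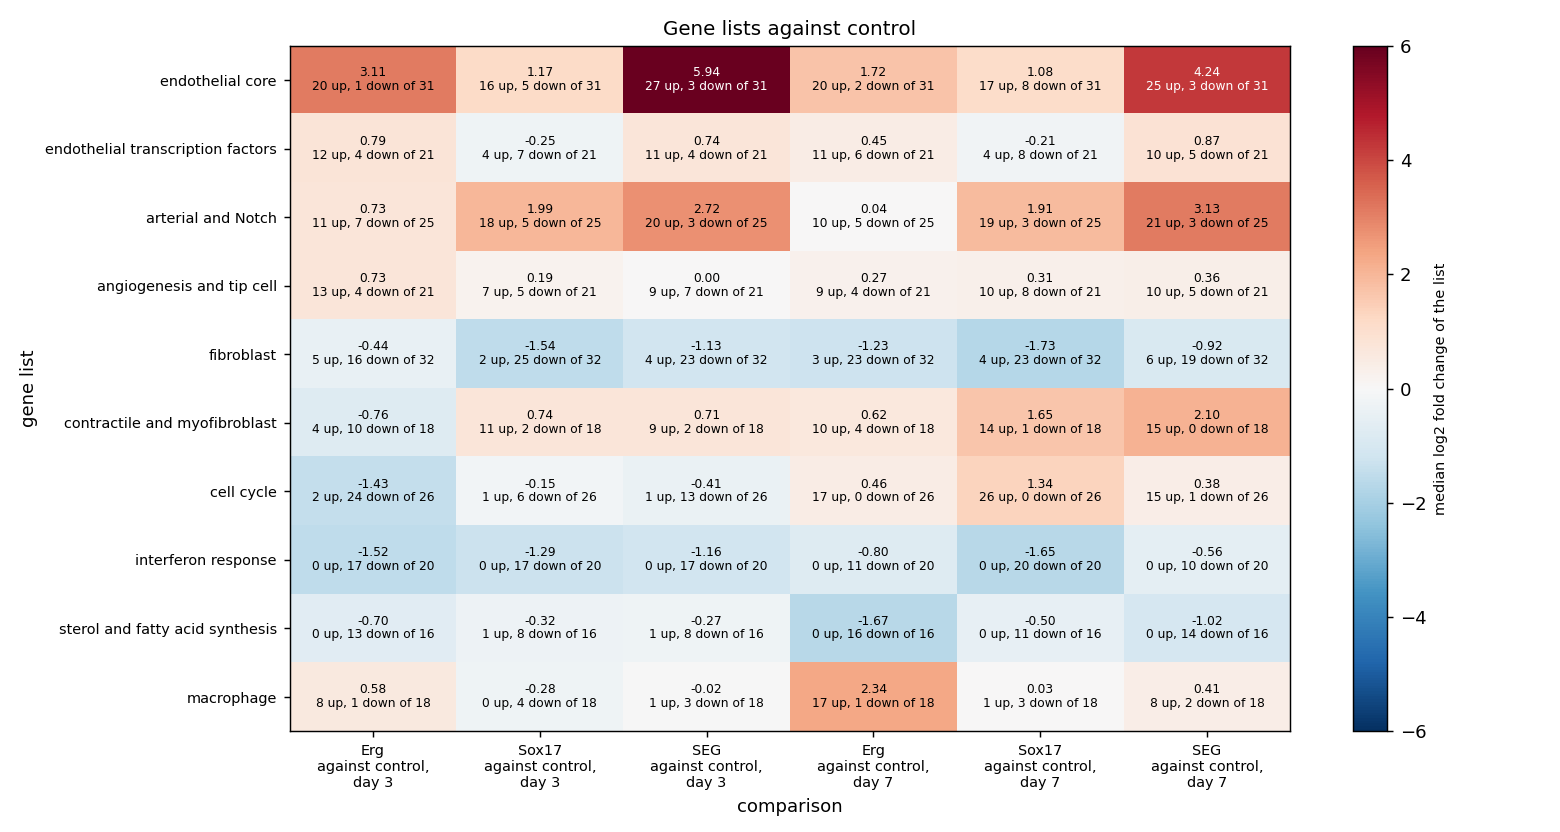
Median log2 change against control of 10 gene lists (rows) with Erg, Sox17 and SEG at day 3 and day 7 (columns), coloured by size and direction, with the number of genes that rose and fell printed in each cell. The endothelial core list has its highest medians in SEG (5.94 at day 3 and 4.24 at day 7, or 4.37 and 4.53 with genes at 0 counts at their bound and Nos3 left out at day 7), and the cell cycle list lies at −1.43 with Erg at day 3 and at 1.34 with Sox17 at day 7.

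SEG against Erg asked what SEG cells expressed beyond Erg alone. Erg itself was lower in SEG, at 0.179 times its level with Erg alone at day 3 and 0.187 times at day 7. The comparison is therefore not one at an equal level of Erg. At day 3, log2 changes in favour of SEG were 9.48 for Gja5, 7.76 for Tie1, 7.00 for Dll4, 5.86 for Cdh5 and 4.76 for Pecam1, and all passed. Lower in SEG were Apln (−7.43), Reln, a secreted glycoprotein of lymphatic endothelium (−7.39), Jag2 (−6.75), Lyve1 (−5.33) and Flt1 (−2.98). Of the 31 endothelial core genes, 20 were higher, 7 lower and 4 did not pass, with 21 and 7 adjusted over the list alone (median 1.53, camera adjusted p = 0.00182). Of 25 arterial genes, 20 were higher and 5 lower, alike adjusted over the list alone (median 2.51, camera adjusted p = 1.73e-06, and adjusted p = 0.0502 with an estimated correlation). Cell cycle genes were higher in SEG, 22 of 26 with 2 lower, and alike adjusted over the list alone (camera adjusted p = 2.7e-06, and adjusted p = 0.0524 with an estimated correlation). Macrophage genes had a median of −0.568. Of 24 genes of another macrophage list, used for a check below, 11 were lower in SEG and 1 higher (median −0.626). Called genes numbered 3809 higher and 3742 lower.

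At day 7, SEG exceeded Erg by 10.97 for Sema3g, 10.23 for Dll4, 9.90 for Tie1, 7.76 for Cdh5, 6.58 for Pecam1 and 4.53 for Vwf on the log2 scale, whereas Flt1 had a log2 change of −0.35 (adjusted p = 0.201). Among the 31 endothelial core genes, 22 were higher and 7 lower, with 23 and 7 adjusted over the list alone (median 2.61, camera adjusted p = 4.4e-06), and of 25 arterial genes 20 were higher and 4 lower, alike adjusted over the list alone (median 3.01, camera adjusted p = 1.52e-09). Macrophage genes were lower in SEG, 16 of 18 with none higher, and 17 adjusted over the list alone (median −1.79, camera adjusted p = 2.41e-07), with Ptprc at −1.24. Contractile genes were higher, 14 of 18 with 1 lower, and alike adjusted over the list alone (median 1.15, camera adjusted p = 9.32e-05), with Acta2 at 2.26. Of 16 sterol and fatty acid genes, 13 were higher and none lower, with 14 adjusted over the list alone (camera adjusted p = 2.33e-05, and adjusted p = 0.13 with an estimated correlation). Called genes numbered 3652 higher and 3668 lower.

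SEG against Sox17 asked the same of the other factor. At day 3, Cd93, a lectin-like receptor of endothelium, stood at 454 ± 53.3 CPM in SEG (log2 change 8.16), and SEG exceeded Sox17 by 9.13 for Dll4, 7.07 for Tie1, 6.98 for Gja5, 5.05 for Pecam1 and 1.92 for Cdh5. In the endothelial core list of 31, 22 were higher and none lower, with 24 adjusted over the list alone (median 2.13, camera adjusted p = 2.66e-16). Of 21 endothelial transcription factors, 14 were higher and 1 lower, with 15 and 1 adjusted over the list alone (camera adjusted p = 3.69e-09, and adjusted p = 0.115 with an estimated correlation). Of 25 arterial genes, 19 were higher and 2 lower, alike adjusted over the list alone (camera adjusted p = 1.23e-08). Called genes numbered 2075 higher and 2109 lower, 4184 together, against 6570 in a fit of only the groups compared and 7275 without both outlying day 7 libraries.

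At day 7, SEG exceeded Sox17 by 8.60 for Dll4, 8.49 for Adgrf5, an adhesion receptor of endothelium, 8.33 for Robo4, 6.83 for Tie1, 6.10 for Pecam1, 3.62 for Gja5 and 2.74 for Cdh5, and Cldn5 was at least 225-fold higher. Penk, a precursor of enkephalins, stood at 438 ± 140 CPM with Sox17 (−12.03), and Cnn1 had a log2 change of −5.37. Of the 31 endothelial core genes, 24 were higher and 1 lower, with 25 and 1 adjusted over the list alone (median 2.83, camera adjusted p = 3.69e-15), and of 25 arterial genes 21 were higher and 2 lower, alike adjusted over the list alone (camera adjusted p = 5.87e-09). Cell cycle genes were lower in SEG, 24 of 26 with none higher, and 24 adjusted over the list alone (median −0.85, camera adjusted p = 1.39e-10). Of 20 interferon genes, 13 were higher and none lower, with 15 adjusted over the list alone (camera adjusted p = 0.000178, and adjusted p = 0.387 with an estimated correlation). Macrophage genes had a median of 0.427, and of 24 genes of the other macrophage list 12 were higher and 2 lower (median 0.642). Camera calls of the macrophage and pericyte lists with the preset correlation did not hold in every alternative (highest adjusted p = 0.214 and 0.0751). Called genes numbered 2776 higher and 3134 lower, 5910 together, against 2174 in a fit of only the groups compared. Replicate 1 of both groups held the outlying ribosomal protein shares, 7.23% with Sox17 and 4.99% in SEG.

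SEG against the sum of both factors asked whether the change in SEG differed from the added log2 changes of Erg and Sox17. At day 7, Dll4 lay 7.19 log2 units above that sum, Cd93 4.99, Pecam1 4.93, Vwf 4.03 and Emcn 1.99, and all passed. Kdr lay at −4.49 and Cdh5 at −1.94 (adjusted p = 0.0115), below it, as did Acta2 (−2.83). Col1a1 lay 2.52 above. At day 3, Adgrl4, an adhesion receptor of endothelium, lay 6.38 above and Cd93 5.41, whereas Kdr lay at −6.61, Cdh5 at −2.48 and Flt1 at −1.70. Cdh5 was nonetheless higher in SEG than with either factor alone at both days. Its log2 effects, which the sum adds, are taken over a very low control level. The sum also takes each factor at its level alone. In SEG, Erg stood at 0.179 and 0.187 times that level at day 3 and day 7, and Sox17 at 0.628 and 0.647 times. Whether these levels bear on genes below the sum was not tested. Among the 31 endothelial core genes, 18 at each day had CPM in every SEG library above every library of both single factors. Were the conditions alike, 1.19% of genes would do so. The share among all tested genes was not computed. SEG differed from Erg for 51.01% and 49.45% of them at day 3 and day 7, and from Sox17 for 28.26% and 39.92%. The 1.19% thus does not set the list apart from other genes. Of all 31, 10 were called above the sum of log2 effects and 10 below at day 3, and 15 above and 7 below at day 7. Against the linear sum of CPM, Erg plus Sox17 minus control, taken from the libraries least in favour, 16 of the 31 lay above and 8 below at day 3, and 19 above and 6 below at day 7; for a gene that rises with both factors this is the lower of the sums. Called genes numbered 2696 above and 2630 below at day 3, 5326 together, and 3519 above and 3700 below at day 7. At day 3 a fit of only the groups compared called 8265, and the fit without both outlying day 7 libraries 8233.

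Day 7 against day 3 within a condition asked how expression moved with time. In control, cell cycle genes fell, 26 of 26, also adjusted over the list alone (median −2.08, camera adjusted p = 4.08e-33), with Mki67 down, at a log2 change of −2.39. Contractile genes fell, 15 of 18 with none rising, and 16 adjusted over the list alone (median −0.92, camera adjusted p = 6.99e-11), with Tagln at −3.15. Interferon genes rose, 17 of 20 with none falling, and 19 adjusted over the list alone, with Irf7, a regulator of interferon genes, at 3.37 (camera adjusted p = 3.75e-08, and adjusted p = 0.153 with an estimated correlation). Of 16 inflammatory genes, 12 rose and 2 fell, with 12 and 3 adjusted over the list alone (camera adjusted p = 1.71e-06), with C3 at 3.08. Gsn rose by 2.64, to 11600 ± 727 CPM. Called genes numbered 2385 higher and 1983 lower, 4368 together, against 7856 in a fit of only the groups compared and 7359 without both outlying day 7 libraries.

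With Erg, macrophage genes rose from day 3 to day 7, 18 of 18, also adjusted over the list alone (median 2.42, camera adjusted p = 2.19e-18), with C1qc, a complement component of macrophages, at 81.2 ± 5.08 against 8.79 ± 0.509 CPM and Siglec1, a sialic acid receptor of macrophages, up by 3.69. Sterol and fatty acid genes fell, 16 of 16, also adjusted over the list alone (median −1.74, camera adjusted p = 8.17e-23), and Cdh5 fell by 1.41. Macrophage genes rose over the same time in control, 10 of 18 with none falling, and 13 adjusted over the list alone (camera adjusted p = 0.000101, and adjusted p = 0.11 with an estimated correlation). Called genes with Erg numbered 2316 higher and 2131 lower, 4447 together, against 7058 in a fit of only the groups compared and 8162 without both outlying day 7 libraries.

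With Sox17, Penk rose by 7.36 and Gja5 by 3.91 from day 3 to day 7. Cell cycle genes fell, 17 of 26 with none rising, and 19 adjusted over the list alone (median −0.40, camera adjusted p = 3.6e-07). Macrophage genes rose, 11 of 18 with none falling, and 12 adjusted over the list alone (median 1.05, camera adjusted p = 1.44e-06, and adjusted p = 0.0709 with an estimated correlation). Replicate 1 at day 7 is one of the outlying libraries. Called genes numbered 2455 higher and 1913 lower, 4368 together, against 857 in a fit of only the groups compared. In SEG, Vwf rose by 4.24, Sema3g by 3.78, Hey1 by 2.08, Pecam1 by 1.52, Dll4 by 1.38 and Tie1 by 1.27. In the endothelial core list of 31, 13 rose, 2 fell and 16 did not pass, with 15 and 3 adjusted over the list alone (median 0.49, camera adjusted p = 0.0052). Of 25 arterial genes, 12 rose and 2 fell, alike adjusted over the list alone (camera adjusted p = 0.000699, and adjusted p = 0.113 with an estimated correlation). Macrophage genes rose, 14 of 18 with none falling, and 15 adjusted over the list alone (median 1.36, camera adjusted p = 1.89e-08), and interferon genes 19 of 20, with 20 adjusted over the list alone (camera adjusted p = 2.68e-16). Cell cycle genes fell, 26 of 26, also adjusted over the list alone (median −1.01, camera adjusted p = 2.12e-20). Called genes numbered 2110 higher and 1914 lower, 4024 together, against 6761 without both outlying day 7 libraries.

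The effect of each factor at day 7 against its effect at day 3 asked whether the difference from control moved with time. The Erg effect on Acta2 was higher at day 7 by 2.87 log2 units and that on Mki67 by 2.01, and that on Dcn was lower (−1.71). The Sox17 effect was higher at day 7 for Pdgfb (4.11) and Acta2 (2.76) and lower for Adamts15, a metalloproteinase (−5.40). The SEG effect was higher at day 7 for Sema3g (4.67), Vwf (3.70) and Acta2 (2.79) and lower for Gsn (−2.80). All these effects share the control libraries, in which Gsn rose and Mki67 and contractile genes fell between the days. A moved effect can therefore lie in control as well as in the cells with the factor. Of the genes tested by edgeR, 2916 passed for Erg, 2113 for Sox17 and 1756 for SEG. A fit of only the groups compared called 6442, 1129 and 2746, and the fit without both outlying day 7 libraries 6593, 3695 and 3774. Without replicate 3 of Sox17 at day 7, 3199 passed for Sox17.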

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

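The test for a mix-up of labels, both comparisons of factor levels between SEG and the factor alone and the splits within 1 day alone were chosen only after the results were seen. Effects of a factor that differed between day 3 and day 7 by a test of the difference itself are listed first.

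The Erg effect differed between the days for 2916 genes, the Sox17 effect for 2113 and the SEG effect for 1756 (edgeR). The Erg effect was higher at day 7 for Fbxo2, a ubiquitin ligase subunit, by 4.92 log2 units, for Acta2 by 2.87 and for Mki67 by 2.01. It was lower for Igfbp5, an insulin-like growth factor binding protein (−4.99), Lrg1, a secreted glycoprotein (−4.75), Flt1 (−2.43) and Dcn (−1.71). The Sox17 effect was higher at day 7 for Cnn1 (4.25), Pdgfb (4.11) and Acta2 (2.76), and lower for Adamts15 (−5.40), Gsn (−2.67) and Kdr (−1.91). The Kdr difference did not pass without replicate 3 of control at day 3 (−1.67), without replicate 3 of control at day 7 (−1.63), in a fit of only the groups compared (−1.93) or beyond 1.5-fold. The SEG effect was higher at day 7 for Mmp9, a matrix metalloproteinase (5.99), Adgrf5 (5.02), Sema3g (4.67), Vwf (3.70), Acta2 (2.79) and Hey1 (2.42), and lower for Hp (−4.71) and Gsn (−2.80). Control itself moved between the days, with Gsn higher and Mki67 and contractile genes lower at day 7. The moved effects on Gsn, Mki67, Acta2 and Cnn1 can therefore lie in control. Without replicate 3 of Sox17 at day 7, 3199 genes passed for the Sox17 effect.

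Replicate 1 of Sox17 at day 7 stood apart from its group, and its log2 ratio to the other libraries followed transcript length across genes, which are not independent replicates (Spearman's rho −0.683, −0.672 log2 units per doubling of length). Its correlation was highest with its own group (r = 0.9449, against 0.9337 for Sox17 at day 3), which argues against a wrong label. Among 4 lists of other cell types (macrophage, cardiomyocyte, pericyte and epicardial), the highest median ratio was 0.405, for macrophage genes. These medians were not corrected for transcript length and cover no further cell types, so they do not decide on cells of another type. Length bias of the library is a candidate explanation. Ribosomal protein genes lay at 1.40, and 442 other genes, limited to short and well expressed ones, at 0.69. Those genes were bounded on 1 side only in length and in expression. Whether length accounts for all of the rise of ribosomal protein genes therefore stays open. Replicate 1 of SEG at day 7 followed length too (rho −0.720, −0.331 per doubling), and the deviations of both libraries correlated at 0.69 across genes. The relation is not confined to them: rho was at least 0.3 in size in 12 of 24 libraries, 6 of them in other groups. It was −0.687 in replicate 3 of Erg at day 7, although slopes in those groups were at most 0.16 per doubling in size. Each ratio was taken against the other libraries of the group, so 1 biased library gives the others an opposite rho. Replicates 2 and 3 of Sox17 at day 7 had 0.645 and 0.693. The 12 are therefore not a count of biased libraries. What brought the bias about stays open, and no biological explanation was tested.

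Macrophage genes were higher with Erg at day 7. All 24 genes of another macrophage list, not used before, rose (median 2.50, against 2.34 for the first list). With RLE size factors the first median was 2.38. RLE shifted the median change of all genes by only 0.0331, so it could not have removed such a rise, and this check does not decide on scaling. In the main fit the median over all tested genes was −0.0152, so the list rose relative to the other genes. At day 3 with Erg, 14 of the 24 rose and 2 fell (median 0.841, against 0.583 for the first list, whose call did not hold with an estimated correlation). A larger share of macrophages in these cultures is a candidate explanation, with Lyz2 at 368 CPM and C1qb at 102 CPM as the most abundant genes of the list, although Cd14 was lower, at 2.63 against 3.99 CPM. Control expressed 8 of the 18 genes at 10 CPM or more at day 7, and the labels name no sort that would remove macrophages. Whether cells of that type grew in number or the same cells expressed these genes more stays open.

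Of 31 endothelial core genes, 15 in SEG were called above the sum of both log2 effects at day 7 and 7 below it, and at day 3 10 above and 10 below. The list as a whole was not tested against the sum, and the days were not compared. At day 7, 19 of 31 lay above the linear sum of CPM of both factors alone, but for a gene that rises with both factors the linear sum is the lower bar, and it was the higher bar for only 11 of 31, so that count does not decide on the log2 scale, whose part stays open. Erg stood at 0.187 times its level with Erg alone, which argues against a higher level of Erg in SEG. Sox17 stood at 0.647 times its level with Sox17 alone (log2 change −0.628, SE 0.283, adjusted p = 0.0909) and was lower in all 14 alternative fits (−0.908 to −0.4), with a call without replicate 1 of Sox17, without both outlying libraries and with the block within both groups. That argues against a higher level of Sox17, although replicate 1 of Sox17, at 615.6 CPM, lay below 2 libraries of SEG. The sum takes Erg at a higher level than SEG holds, so it is not a sum at equal levels. The labels do not say whether SEG holds a further factor, which would change what the sum means. A further factor and a joint effect of Erg and Sox17 stay open, and neither was tested.

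The comparisons of 3 libraries with 3 have 10 splits each, too few for a share under 0.05, and in each of them 1 split, the real one, gave as many calls. The real counts and the highest of the other splits were 6827 and 0 for Erg against control at day 3, 5987 and 0 for Sox17, 5946 and 0 for SEG, and at day 7 7182 and 1, 8062 and 24, and 6557 and 0. For SEG against Erg they were 7551 and 1 at day 3 and 7320 and 1 at day 7, and for SEG against Sox17 4184 and 4, and 5910 and 4930. Between the days they were 4368 and 0 in control, 4447 and 0 with Erg, 4368 and 2058 with Sox17, and 4024 and 0 in SEG. The splits with 4930 and 2058 calls exchange libraries of which replicate 1 of Sox17 at day 7 or of SEG at day 7 is one, which points to a structure of the samples. For the effects between days and the sums, 30 splits were drawn. Both real sums (5326 at day 3 and 7219 at day 7) had as many calls in 1 of 30, with 1988 and 4179 as the highest other. These splits drew the libraries of a day anew over all 4 conditions. They exclude, at that share, only that no condition differed, and cannot decide on a departure from the sum. The drawn splits gave as many calls in 1 of 30 for the Erg effect (2916, highest other 1049), in 2 of 30 for the Sox17 effect (2113, highest other 5699) and in 4 of 30 for the SEG effect (1756, highest other 4309). The 30 drawn for Erg held none of the 19 splits that exchange 4 or 6 factor and control libraries in 1 day alone, against 1 for Sox17 and 3 for SEG. All 19, run apart, gave as many calls as the real split for each effect (3833 to 8458 for Erg), at least 10% of the 200 splits. Such splits make a difference between days out of the factor's effect itself, a structure of the samples. Their outcome follows from that effect, so the count of splits cannot decide on chance for any of the effects.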

How the results depend on the processing

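Leaving out both outlying day 7 libraries and the replicate block within Sox17 and SEG at day 7 were chosen only after the data were seen; the other alternatives were planned. No called gene of a comparison was called the other way under any alternative, though the value of Tie1, given below, changed sign in 1 fit. RLE size factors, no filter, the replicate block and DESeq2 left each count of calls within 1.5 times its value. The lower counts beyond 1.5-fold follow from the stricter threshold. For the other values below the cause was not tested, but the main fit shares 1 spread over groups that differ in it. Chi-square per degree of freedom between counts was 463 and 458 for replicate 1 of Sox17 at day 7 against the others of its group. Between replicates 2 and 3 it was 7.29. With that library in, p-values may be too small for Sox17 at day 7 and too large for other groups.

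Beyond 1.5-fold, calls numbered 3090, 2863 and 2580 at day 3 and 3167, 3968 and 3164 at day 7 for Erg, Sox17 and SEG against control. They numbered 3595 and 3550 for SEG against Erg, 1530 and 2344 for SEG against Sox17, and 1308, 1234, 1023 and 1253 between the days in control, Erg, Sox17 and SEG. For the effects between days they were 814, 638 and 502, and for the sums 2534 and 3833. A fit of only the groups compared called 4314 for Sox17 against control at day 7, 6570 and 2174 for SEG against Sox17, 7856, 7058 and 857 between the days in control, Erg and Sox17, 6442, 1129 and 2746 for the effects between days, and 8265 for the sum at day 3. Without both outlying day 7 libraries the counts that moved were 7275 for SEG against Sox17 at day 3, 7359, 8162 and 6761 between days in control, Erg and SEG, 6593, 3695 and 3774 for the effects and 8233 for the sum at day 3. Their calls between days with Sox17 kept 3736 of 4368.

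Leaving out each library of the groups compared in turn, calls ranged over 6005–6117, 5228–5352 and 5178–5270 at day 3 and 6071–6746, 7171–9027 and 5755–6091 at day 7 against control. They ranged over 6755–6817 and 6507–7399 for SEG against Erg, 3490–3587 and 4798–7229 for SEG against Sox17, and 3503–3695, 3462–3798, 3191–6021 and 3283–3669 between the days in control, Erg, Sox17 and SEG. For the effects they ranged over 2339–2577, 1592–3199 and 1394–1575, and for the sums over 4732–4909 and 6328–8353. Libraries of other groups share the spread, but were not left out for these ranges, which therefore understate how far the counts can move. Without both outlying day 7 libraries, calls against control at day 3 numbered 9478 for Erg, 8649 for Sox17 and 8605 for SEG. List calls ranged over 121–128 of the 308. In each fit all 23 libraries left fell on the side their label names, with SEG taken to name both factors. Of 124 list calls 50 held with the estimated correlation, 111 without both outlying libraries (120 called in all), 124 with RLE and 122 with no filter (137 called in all).

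With a replicate block list calls came to 123. The check of the pairing found that same-numbered libraries deviated together in 9 of 84 pairs (r over 0.1, median r 0.00276), and in 28 of 84 the own number was the best match, so numbers do not pair the libraries over the whole design. Sox17 and SEG at day 7 differ from that: all 3 same-numbered pairs deviated together (r = 0.690, 0.396 and 0.441), each above its best match under another number (−0.464, 0.390 and 0.418), by little for replicates 2 and 3. This is a hint from the data, not from the design, and replicate 1 is the outlying library of both groups. Deviations from a group mean balance out within the group, so replicates 2 and 3 deviate opposite to replicate 1 in both. The 3 pairs are therefore not independent, and the hint rests on replicate 1. With a replicate block within these groups alone, SEG against Sox17 at day 7 had 8387 calls against 5910, of which 5907 were kept, and list calls came to 123. Tie1, for SEG against the sum at day 7, ranged from −0.00657, without replicate 2 of control at day 7, to 4.04, against 3.42. Depth limits genes at 0 counts in a group, for which only a bound can be given.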

Other observations

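The values here come from lists of other cell types and pathways that were fixed before the data were examined, and no test was chosen after its result was seen. Genes of cartilage and bone fell with Sox17 at day 3, 7 of 10 with 2 rising, and 7 and 3 adjusted over the list alone (median log2 change −2.03, camera adjusted p = 0.00558, and adjusted p = 0.119 with an estimated correlation). Alpl, an alkaline phosphatase of bone, fell by 4.65, and Sox9 stood at 10.8 ± 1.32 against 152 ± 0.957 CPM (SD, n = 3). In SEG at day 3, 6 of the 10 fell and 1 rose, with 6 and 1 adjusted over the list alone (camera adjusted p = 0.0149, and adjusted p = 0.18 with an estimated correlation). Of 9 epicardial and mesothelial genes, 6 fell and 1 rose with Sox17 at day 3 (camera adjusted p = 0.0264, and adjusted p = 0.119 with an estimated correlation) and 7 fell and 1 rose in SEG (camera adjusted p = 0.019, and adjusted p = 0.12 with an estimated correlation), alike adjusted over the list alone. Aldh1a2, a retinaldehyde dehydrogenase, fell to 11.4 ± 0.865 from 45.5 ± 3.28 CPM with Sox17, and Msln, mesothelin, by 3.40 in SEG. Lpl, lipoprotein lipase, rose with Erg at day 3 to 1271 ± 61.1 against 641 ± 36.1 CPM and fell in SEG to 113 ± 4.62, and Pparg, a regulator of adipocytes, rose by 1.12 with Erg. Of 6 adipogenic genes, 4 rose and none fell with Erg at day 3, alike adjusted over the list alone (camera adjusted p = 0.0266, and adjusted p = 0.177 with an estimated correlation).

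Genes of the p53 response and senescence rose from day 3 to day 7, 9 of 14 in control (camera adjusted p = 0.00335), 7 of 14 with Sox17 (0.00121) and 8 of 14 in SEG (0.000359), with none falling, and 9, 9 and 8 adjusted over the list alone. With Erg 5 of 14 rose, without a camera call (adjusted p = 0.119). Cdkn2a, an inhibitor of cyclin-dependent kinases, rose by 1.02 in control and by 2.05 in SEG, to 89.2 ± 24.4 CPM. Tnnt2, a cardiac troponin, stood at 5.93 ± 0.634 CPM in SEG against 54.5 ± 2.02 in control at day 3 and at 12.4 ± 3.03 against 83.0 ± 9.87 at day 7. Of 6 cardiomyocyte genes, 1 fell and 2 rose in SEG at day 3, without a camera call (adjusted p = 0.759). Ndrg1, a gene induced by low oxygen, reached 179 ± 1.82 against 7.86 ± 0.755 CPM with Erg at day 3, and camera did not call the 13 genes of glycolysis and hypoxia (adjusted p = 0.421), of which 7 rose and 5 fell.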
